A study of Caenorhabditis elegans
Pristionchus pacificus with 6 samples.

How the data were processed

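RNA-seq was done on dissected anterior intestines of adult C. elegans, dissected 72 hours after egg lay at 20 °C, with P. pacificus intestine lysate (dissected at 96 hours) added, per the labels' protocols. Libraries were made with a low-input kit and sequenced with paired reads. The authors deposited 1 table of raw counts per gene for both species, with whole numbers and no normalization. STAR (an aligner) and featureCounts (a read counter) are named in the submitters' processing notes. Versions, genome builds and annotation are not given in the sources used here, nor is it stated whether counting used strand. The name of the deposited table says that multi-mapping reads were left out of the counts.

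Columns were matched to samples through their names, which the labels repeat, and groups came from the sample titles (3 control, 3 CDK-2gut(-)). All 73268 rows carry a gene identifier, and 0 of these identifiers occur in the C. elegans gene table used here, so gene symbols were not assigned. For this reason the 35 gene lists fixed by symbol were not tested, and the levels of cdk-2, zif-1 and asp-1 in each library were not analysed here. The rule for named genes was fixed before the data were examined: the called genes with the largest fold in each direction among those with a mean of at least 100 counts and no overlap between groups. Of these, 2 per direction in the composition fit are printed.

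The table does not state which species a row belongs to. This was inferred from the counts. A change point in file order was sought in the profiles across libraries of 5621 genes with at least 50 counts in every library, using a multivariate normal likelihood. It fell between rows 46936 and 46959, the nearest such genes on either side, and last rows from 46912 to 46958 lay within 3 log-likelihood units. Row 46958 was taken as the last of the first block. In the 26310 rows after it, control and CDK-2gut(-) libraries of the same number differed by a robust SD of 0.22, 0.23 and 0.25 in log2 ratio, against a median sampling SD of 0.13 to 0.15. In the rows before it they differed by 0.65, 0.69 and 0.72. The later rows thus behaved as 1 lysate split between the strains and were taken as P. pacificus. All statements on species rest on this inference. The size of the C. elegans gene table, 46926, was tried as another boundary, which moved 4011 counts.

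C. elegans counts ranged from 9432973 to 15874554 per library and P. pacificus counts from 1761793 to 4060591. At this depth the sampling error of the log2 ratio is at most 0.0012, which covers counting error only. Genes were kept with edgeR's filterByExpr within each species, which left 8309 C. elegans and 6645 P. pacificus genes. The main tests were edgeR (version 4.0.16, R 4.3.3) robust quasi-likelihood tests with Benjamini-Hochberg adjustment at 0.05. The spike-in-scaled fit used P. pacificus totals times TMM factors over P. pacificus genes as library sizes. The composition fit used TMM factors over C. elegans genes. Standard errors are the log2 fold divided by the square root of F. An error in the spike-in scale is shared by all genes, so the spike-in-scaled calls are not independent of each other. Sums and shares per library were compared with two-sided exact permutation tests, and within replicate numbers with exact sign-flip permutation tests. For the expression groups, log2 values used a prior count of 2.

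Whether the replicate numbers pair the libraries was checked from deviations from the group means before the fits were compared. Over P. pacificus genes, libraries with the same number correlated at 0.74, 0.74 and 0.93 for numbers 1, 2 and 3. Each exceeded the threshold of 0.1 used here, so the spike-in fit was also run with the replicate number as a block. The values reported are from the fit without it. Control 1 with CDK-2gut(-) 2 and control 2 with CDK-2gut(-) 1 correlated as highly, at 0.74 and 0.72, so the profiles set number 3 apart and do not tell 1 from 2. Over C. elegans genes the correlations were 0.02, -0.10 and 0.34, so only number 3 passed the threshold. Control 2 with CDK-2gut(-) 1, of different numbers, correlated at 0.37, and control 3 with CDK-2gut(-) 1 at -0.37. For C. elegans genes the numbers were therefore not taken as pairs, though a pairing of number 3 stays open.

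The fits were tested on simulated data for 8309 genes with the means of these libraries and the dispersions of the composition fit. The common biological coefficient of variation was 0.392 in that fit and 0.475 in the spike-in-scaled fit. Composition simulations used the sizes of these libraries. Spike-in simulations gave both strains of a replicate number the same baseline ratio of C. elegans counts to spike-in. With 200 changed genes, the composition fit recovered 1 of 67 genes changed 1.5-fold, 1 of 67 changed 2-fold and 25 of 66 changed 4-fold. It also called 7 of 8109 unchanged genes. Set against the 1, 1 and 25 recovered genes, these 7 exceed the share of false calls of 0.05 that the adjustment aims at. In the data the composition fit called 1548 genes. With only 200 changed genes the adjustment is stricter, so the recovered shares do not give the power of the fit in these libraries. With every C. elegans gene at 0.5 times control relative to the spike-in, the spike-in-scaled fit called 2486 genes lower and 5 higher, with a median log2 fold of -1.00. With no change it called 0 genes. This does not cover an error in the spike-in scale between strains, which was not simulated. Alternatives covered DESeq2 (1.42.0), limma-voom (limma 3.58.1), other scalings and filters, a fold threshold, a stricter adjusted p, the replicate number as a block and leaving out each library. Leaving out replicate 3 of both strains, the other boundary and thinning were added after seeing the data.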

Results

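RNA from dissected anterior intestines of adult C. elegans hermaphrodites was sequenced from a control strain and from a strain with reduced intestinal ploidy, named CDK-2gut(-). Intestinal cells of this nematode normally become polyploid by repeated rounds of genome duplication. Both strains carried a tagged copy of the cell cycle kinase gene cdk-2 and a zif-1 mutation. The CDK-2gut(-) strain also expressed, from the asp-1 promoter, a GFP-binding nanobody fused to ZIF-1, an adaptor that directs tagged protein to degradation. Lysate of intestines from another nematode, Pristionchus pacificus, was added in equal amount to every library's lysate as a spike-in. Which genes of the table belong to which species was inferred from the counts. There were 3 libraries per strain, numbered 1 to 3 in both. The control libraries held 11194766, 13028462 and 13659789 counts, and the CDK-2gut(-) libraries held 18934522, 15302343 and 15334161 counts. The labels do not say that the 3 libraries of a strain came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

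The first comparison asked whether the amount of C. elegans RNA relative to the spike-in differed between the strains. It did not differ detectably. Control libraries held 4.21 ± 1.32 (SD, n = 3) C. elegans counts per P. pacificus count, and CDK-2gut(-) libraries held 4.19 ± 1.26 (SD, n = 3). The log2 ratio differed by -0.0044 between strains (two-sided exact permutation test, p = 1, where 3 libraries against 3 cannot go below 0.1). The ratio followed the replicate number closely. It was 5.35 in control and 5.19 in CDK-2gut(-) replicate 1, 4.51 and 4.61 in replicate 2, and 2.78 and 2.78 in replicate 3. Within a number, CDK-2gut(-) stood at 0.969 to 1.02 times its control, an SD of 0.039 on the log2 scale against 0.49 between control libraries. The spike-in of replicate 3 also stood apart: its P. pacificus genes differed from those of replicates 1 and 2 of the same strain by a robust SD of 0.74 to 0.81 in log2 ratio, against 0.23 and 0.24 between replicates 1 and 2. The number of intestines behind each lysate is not given in the sources used here, so the ratio is one of lysates rather than of single intestines.

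**Figure D1:**
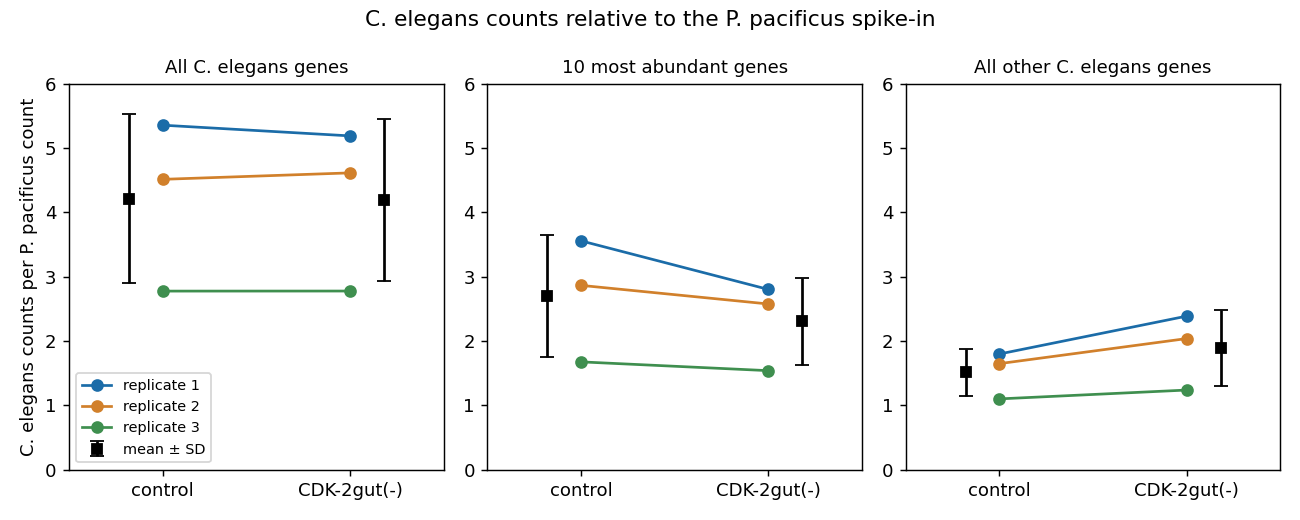
C. elegans counts per P. pacificus count (linear axis from 0) in each library, joined by replicate number, for all C. elegans genes, the 10 genes with the highest mean count and all other genes; black squares are means ± SD of 3 libraries. The total lay between 2.78 and 5.35 in both strains with nearly flat lines, while the 10 most abundant genes sloped down and the other genes sloped up in all 3 replicate numbers. Both groups add up to the total, so their slopes are not independent.

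Within this total, the summed counts of the 10 most abundant genes were lower and those of all other genes higher in CDK-2gut(-), without passing a test per P. pacificus count. The 10 C. elegans genes with the highest mean count took 63.4% ± 3.03 (SD, n = 3) of C. elegans counts in control and 55.1% ± 0.965 (SD, n = 3) in CDK-2gut(-). The share was lower by 8.34 percentage points, and all 3 CDK-2gut(-) libraries lay below all 3 controls (two-sided exact permutation test, p = 0.1, the smallest this design allows). Per P. pacificus count, these 10 genes together stood at 0.866 times control, with fitted log2 folds below 0 for 6 of them. The log2 differences within replicate numbers 1, 2 and 3 were -0.34, -0.15 and -0.12. All other C. elegans genes together stood at 1.23 times control, with log2 differences of 0.41, 0.31 and 0.17. Both sums add up to a total that was nearly flat within each number, so a fall in one goes with a rise in the other. They are not independent results. Neither sum passed a two-sided exact permutation test across strains (p = 0.5 for both), nor a two-sided exact sign-flip permutation test within numbers (p = 0.25 for both, the smallest that 3 pairs allow). Reads that map to several places were left out before deposit, so abundant genes with near-identical copies may be undercounted.

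Gene by gene and scaled to the spike-in, many more C. elegans genes were called higher than lower in CDK-2gut(-). Of 8309 genes tested, 1365 rose and 205 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median gene stood at 1.47 times control, a log2 fold of 0.55, and the quartiles of the log2 folds were 0.10 and 1.09. Log2 folds above 0 were seen for 79.0% of genes. The median log2 fold was 0.34 without control replicate 3, 0.34 without CDK-2gut(-) replicate 1 and 0.79 without control replicate 2. An error in the spike-in scale would move all genes together, so the gene counts do not test this general shift. Over libraries, the median gene outside the 10 most abundant differed by 0.67 in log2 (two-sided exact permutation test, p = 0.2). Within replicate numbers 1, 2 and 3 it differed by 0.78, 0.31 and 0.91 (two-sided exact sign-flip permutation test, p = 0.25). Of the 10 most abundant genes, 1 rose and 1 fell (1 and 2 with the replicate number as a block), and log2 folds ranged from -0.52 to 1.32. P. pacificus genes were tested for single genes that differed between strains, since scaling by their own counts sets their centre near 0. None of 6645 was called between strains by edgeR, with 17 at an unadjusted p under 0.05, and DESeq2 called 0. Those 17 are far below the share of 0.05 that a calibrated test gives without any change, so the 0 calls carry little weight. The spread between replicate numbers widened this test, with a biological coefficient of variation of 0.476 against 0.147 with the replicate number as a block. With that block the count was again 0, with 432 genes at an unadjusted p under 0.05, somewhat above that share. These rows were taken as P. pacificus because libraries of the same number differed little in them, so a low number of calls is partly built in. Scaling to plain P. pacificus totals lowered the number of genes that rose to 710. Without CDK-2gut(-) replicate 1 it was 783, and without CDK-2gut(-) replicate 2 there were 706 higher and 109 lower.

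**Figure D2:**
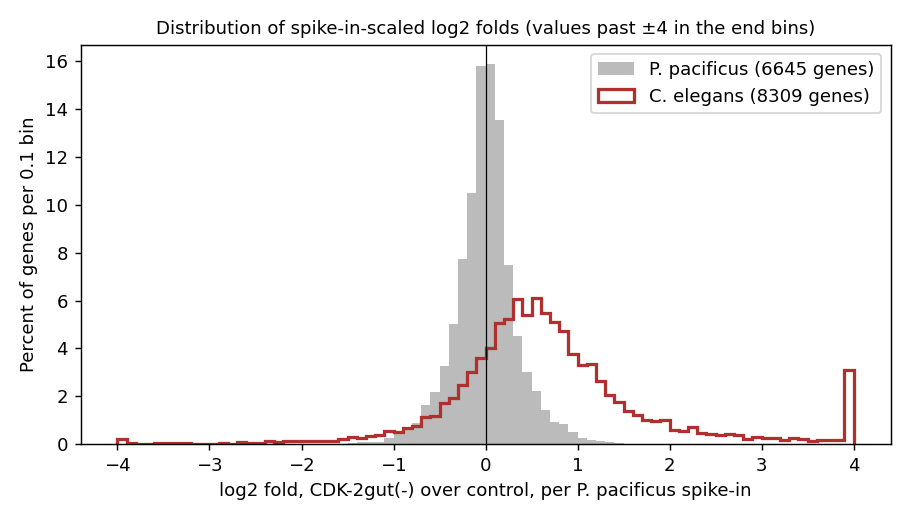
Distribution of log2 folds of CDK-2gut(-) over control for 8309 C. elegans genes (red line) and 6645 P. pacificus genes (grey), both scaled by P. pacificus counts, as the percent of genes per 0.1 bin, with values past ±4 in the end bins. The scaling itself places the P. pacificus genes near 0, and the C. elegans genes had a median of 0.55, with a tail of strongly higher C. elegans genes.

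The second gene-level comparison asked which genes departed from the remainder of the C. elegans transcriptome, after scaling by trimmed mean of M-values over C. elegans genes alone. Of 8309 genes, 980 rose and 568 fell (edgeR quasi-likelihood test, adjusted p under 0.05). The groups were separated without overlap for 38.4% of genes, where chance gives 10%. More than 4-fold changes were called for 463 genes that rose and 133 that fell. Of the 10 most abundant genes, 4 fell and 1 rose. This scaling placed the median log2 fold at 0.10, lower by 0.45 than the spike-in scaling did. The same direction was called in both scalings for 976 genes that rose and 205 that fell, and 0 genes were called in opposite directions. The share of calls that were higher was 86.9% with the spike-in and 63.3% here, and it was 54.2% with median-of-ratios size factors and 85.9% with plain C. elegans totals.

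The genes with the largest changes are given by identifier, since the file does not pair its identifiers with symbols. WBGene00004994 was nearly absent in control, at 3.04 ± 3.04 normalised counts (SD, n = 3), and reached 6558 ± 1587 (SD, n = 3) in CDK-2gut(-). Its log2 fold was 11.13 ± 0.61 (SE), with an edgeR adjusted p of 6.60e-05. This fold rests on 6 counts in control, and it was 12.04 without control replicate 1 and 10.30 without control replicate 2. WBGene00019931 had 0 counts in all 3 controls and 160 ± 17.6 normalised counts (SD, n = 3) in CDK-2gut(-). That is at least 38.1-fold higher against a floor of 3 counts per control library (edgeR adjusted p = 0.00011). In the other direction, WBGene00008829 fell from 3311 ± 956 to 87.2 ± 61.9 normalised counts (SD, n = 3), a log2 fold of -5.26 ± 0.58 (SE; edgeR adjusted p = 0.00201). Without CDK-2gut(-) replicate 3 it was -6.0. WBGene00010706 fell from 900 ± 361 to 32.7 ± 13.7 (SD, n = 3), a log2 fold of -4.80 ± 0.46 (SE; edgeR adjusted p = 0.000665). All 4 genes were also called with the spike-in scaling, with log2 folds of 11.55, 10.51, -4.86 and -4.32 in that order, the second depending on the prior count.

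The composition counts changed with the libraries included. They fell to 555 higher and 327 lower without control replicate 1, and to 645 and 342 without CDK-2gut(-) replicate 1. They fell to 520 and 267 without CDK-2gut(-) replicate 2, and to 507 and 297 without CDK-2gut(-) replicate 3. Without control replicate 2 there were 842 higher and 742 lower, and without control replicate 3 both counts rose, to 1105 and 611. Leaving out a library also lowers the power of the test, and this was not separated from dependence on that library. Without replicate 3 of both strains, 741 rose and 374 fell.

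The last comparison asked whether abundant and rare transcripts changed by the same factor. Genes were ranked by mean spike-in-scaled expression into 10 equal groups. The median log2 fold was 0.74 in the lowest group and 0.44 in the highest, and it lay above 0 in every group and replicate number. In the highest group, of 831 genes, 283 rose and 80 fell with the spike-in scaling, and 161 rose and 166 fell in the composition fit. In the lowest group, 93 rose and 8 fell with the spike-in scaling, and 76 and 14 in the composition fit. The highest group minus the lowest was -0.29. Computed per library, the same contrast differed between strains by -0.27, which was within the spread between libraries (two-sided exact permutation test, p = 0.7). This slope was lost without control replicate 3, where the highest group minus the lowest was 0.02. It was steeper without control replicate 2, at -0.52, and with a prior count of 0.5, at -0.49. The median gene of the lowest group had a mean of 12.7 counts per library.

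**Figure D3:**
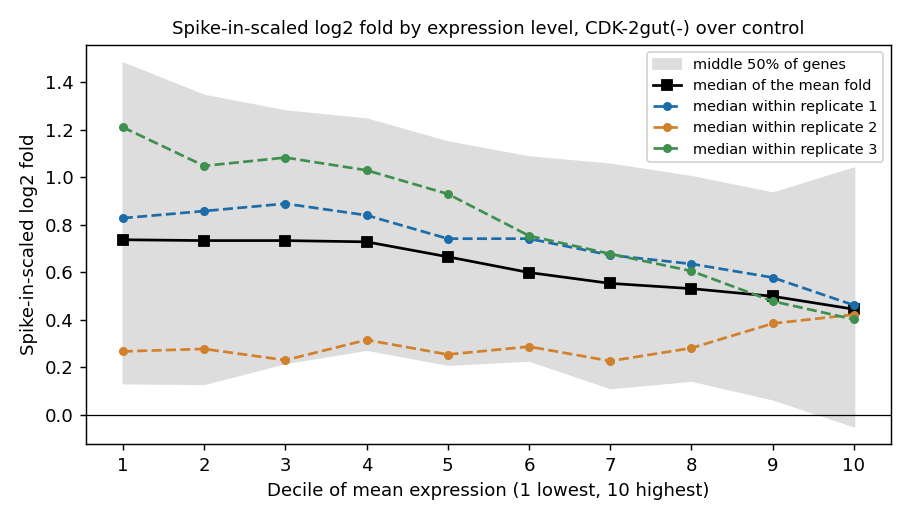
Median spike-in-scaled log2 fold of CDK-2gut(-) over control (vertical axis) in 10 groups of C. elegans genes from lowest to highest mean expression (horizontal axis). Black squares are medians of the fold between group means, the grey band spans the middle 50% of genes, and coloured points are medians within each replicate number; all medians lay above 0, from 0.74 in the lowest group to 0.44 in the highest for the black squares.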

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

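The alternatives without replicate 3 of both strains, with another boundary between species and with thinned libraries were chosen after the data were seen; the other boundary left all 4 counts of called genes as they were. Of the genes called in the main fits, 0 changed direction across 19 settings. This is a weak check. The stricter adjusted p and the tested fold keep the same log2 folds, and the other settings refit the same or most of the same libraries. The log2 difference in the species ratio turned positive without the 10 most abundant genes (0.29), with the P. pacificus total times its TMM factor (0.048) and as a median over C. elegans genes (0.69), and ranged from -0.28 to 0.27 when single libraries were left out. The spike-in-scaled median log2 fold ranged from 0.34 to 0.79 when single libraries were left out and was 0.68 with limma-voom. The composition median was -0.028 with median-of-ratios size factors. The counts of genes lower and higher were as follows. Plain totals gave 1.2e+02 and 710 with the spike-in and 300 and 1830 for composition. A tested fold of 1.5 gave 121 and 839, and 254 and 594. An adjusted p of 0.01 gave 114 and 685, and 257 and 511. Leaving out libraries gave 109 to 246 lower and 706 to 1385 higher with the spike-in, and 267 to 742 lower and 507 to 1105 higher for composition. The difference between highest and lowest expression groups ranged from -0.52 to 0.023. The cause of these shifts was not tested, except that stricter thresholds call fewer genes by construction.

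With the replicate number as a block, the spike-in fit called 241 lower and 1744 higher, with 2 of the 10 most abundant genes lower. For C. elegans composition the numbers were not taken as pairs, and the block gave 489 lower and 845 higher. A further 7 alternatives, on gene lists, vitellogenins and mitochondrial or ribosomal genes, were not run because genes were not matched to symbols.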

Other observations

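In this part the tests on the nearly silent genes, on replicate 3, the thinning and the comparison with pairs over 20 rows apart were chosen after the data were seen.

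By a rule on raw counts, genes that were nearly silent in control and clearly expressed in CDK-2gut(-) had no counterpart in the other direction. There were 72 C. elegans genes with at most 10 counts over the 3 control libraries and at least 50 counts in every CDK-2gut(-) library, 8 of them with 0 counts in control. Their median level in CDK-2gut(-) was 124 counts per library and the highest was 8037. The reverse rule gave 0 genes. The CDK-2gut(-) libraries were deeper, which made the rule easier to meet in the first direction and harder in reverse. C. elegans library sizes times their TMM factors were 7949240 to 10377600 in control and 11845100 to 20072400 in CDK-2gut(-). The rule was not run on scaled counts. The other splits of the 6 libraries into 3 and 3 gave at most 4 genes in either direction. Each of these splits holds CDK-2gut(-) libraries on both sides, so the 72 genes could not meet the rule there. The low number is therefore partly fixed in advance and gives no chance level for the 72.

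Most C. elegans genes stood higher per P. pacificus count while the total did not. Thinning all libraries to the smallest total left 99.8% of the median log2 fold, but it acts alike on both species of a library and moved little else, so it does not decide on the greater depth of the CDK-2gut(-) libraries. A larger lysate input together with a lower level of the abundant genes may account for the pattern, as may the genotype. Neither was tested, nor was carried-over RNA of other tissues.

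The P. pacificus profile of replicate 3 stood apart from replicates 1 and 2 in both strains. A preparation bias acting on both species alike would move C. elegans genes as much, but the smallest P. pacificus spread between replicate 3 and another replicate of the same strain was 1.45 times the largest such C. elegans spread. This argues against such a bias as the whole cause. A part stays open, since C. elegans spreads in control were also wider with replicate 3 (0.47 and 0.51) than between replicates 1 and 2 (0.34). What both replicate 3 libraries shared, such as their portion of P. pacificus lysate, was not tested.

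Changed C. elegans genes lay near each other in file order. Pairs of genes within 5 rows that both rose numbered 327, against a highest value of 250 in 1000 shuffled orders, and pairs that both fell numbered 129 against 102. The correlation of log2 folds was 0.16 within 5 rows, 0.042 at 6 to 20, 0.032 at 21 to 100 and 0.016 beyond that up to 500 rows, all above every shuffled order drawn (200 for the last). Shuffled orders hold no long-range trend and most of the correlation is lost beyond 5 rows, so reads shared between overlapping neighbours stay open as a cause at short range. Leaving out the 100 neighbouring genes with the largest mean change left 94.9% of the correlation within 5 rows, so that window was not its main source. A wider altered region would outlast this removal and stays open. Neighbouring members of gene families that respond together were not tested, and whether file order follows the chromosomes is not stated.

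Other splits of the 6 libraries into 3 and 3 gave 0 genes in either direction and in both scalings, against 205 lower and 1365 higher with the spike-in and 568 lower and 980 higher in the composition fit, so that 1 of 10 splits, the real one, reached each count. The 10 splits are too few for a share under 0.05. Every other split also mixes the strains on both sides. A strain difference then widens the spread within each side and lowers the calls, so 0 genes there is no reference for a lack of effect. Among the splits that part all 3 replicate numbers, the block fit also gave 0 genes in each but the real one, with the same limit.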
